A study of Drosophila melanogaster with 6 samples.

How the data were processed

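RNA from the adult midgut of Oregon-R flies was extracted with TRIzol and made into libraries with the Illumina TruSeq RNA kit, per the labels' protocols, in 3 groups of 2 libraries. Samples were grouped by their titles. The labels number the libraries of each group but do not say whether they came from separate dissections. P-values of single genes thus measure the spread between these libraries, which may be technical. Those of the gene list tests compare a list's genes with other genes and do not measure that spread.

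The submitters' processing notes name CASAVA 1.8, fastp 0.19.5, Salmon 0.11.3 and DESeq2 1.22.0 with build BDGP6; the role and options of each, the annotation release and any use of strand are not given in the sources used here. The deposited file is a single table of the authors' own comparisons with 14026 genes. Per the file headers it holds for each gene a mean signal over all libraries (reads divided by a size factor per library), and, for 2 comparisons, a log2 fold change with its standard error, a score (the Wald statistic, equal to fold change over standard error), a p-value and an adjusted p-value. The deposited fold changes were taken as not shrunk. They equal the score times the standard error to within 2e-13, which does not by itself show this. In 2018 genes the deposited mean is 0. The authors' adjusted p-values equal the Benjamini-Hochberg adjustment over the 10393 genes with a mean of at least 1.24 in the first comparison and the 8316 with at least 20.8 in the second; below those means they are blank and were left blank. The header names no groups. All 652 genes with a fold change of 0 and p of 1 in the second comparison lie above 0 in the first, and all 153 such genes the other way round, so both share a reference group; that the first is Pe day 0 and the second Pe day 3, both against Mock, was read from the order of the groups in the table's title and has no other source.

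An analysis of counts per library had been planned. The table holds none, so the authors' deposited log2 fold changes and adjusted p-values became the main results for both comparisons with Mock, and the following was computed from them. Size factors came from genes with a single read, whose mean is 1 read divided by 6 times the size factor: 0.849 and 0.788 for Mock, 1.43 and 1.42 for Pe day 0, 0.902 and 0.815 for Pe day 3, from 42 to 165 genes each. Group means followed from the overall mean and both fold changes. Multiplying their sums by the size factors estimated 1.90e7 and 1.76e7 reads for the Mock libraries, 2.01e7 and 2.00e7 for Pe day 0, and 1.97e7 and 1.78e7 for Pe day 3. These depths give each group's total, not its spread between libraries. The dispersion that yields each standard error was solved separately from both comparisons; the values had a correlation of 1.00 across genes on the log scale, and their ratio lay between 0.988 and 1.01 in the central 98% of genes (1st to 99th percentile). With it, the variance shared through Mock was removed to give the standard error of Pe day 3 against Pe day 0, whose median was 0.701 of the bound that ignores sharing, and a joint Wald test among all groups. Both used 2-sided normal p-values with Benjamini-Hochberg adjustment over 8316 genes. On simulated data for Pe day 3 against Pe day 0 over 8309 genes the step recovered 41.8% of 67 genes changed 1.5-fold, 87.9% of 66 changed 2-fold and 100% of 66 changed 4-fold, with 11 calls among unchanged genes; the simulation takes the dispersion as known and uses the same variance formula, so it tests the algebra rather than the model.

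Lists of genes, 31 in all, were fixed before the data were examined and tested where at least 4 members were tested. The test was camera on the Wald statistics (cameraPR of limma 3.58.1 in R 4.3.3) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists; no correlation could be estimated without values per library, so the calls with an estimated correlation are unknown, and a preset correlation of 0.05 and ranks were tried. The P450 list was set by symbol and also takes in Cyp1, a cyclophilin. Counts of called members were also made with p adjusted over the list alone; they were the same in 22 of 31 lists at day 0, 23 of 29 at day 3 and 22 of 29 between the days, and the text gives the other counts for lists it dwells on. The named genes were set by a rule fixed with the lists: in each comparison the 6 genes that rose and the 6 that fell most among those called, with at least 10 CPM in the higher group and a symbol not of a numbered form, a panel of 19 genes, and within each list the 2 members with the smallest p and, where a list goes both ways, the member with the smallest p in each direction. The rule also asked that libraries of one group all lie above the other, which the table cannot show. Hsp70Aa and Rcd-1r have 0 estimated reads in Mock and are given as bounds against 3 counts over the group, which cover counting error only. Coordinates come from the Ensembl 115 annotation of BDGP6.54, in which 13928 of the 14026 gene identifiers were found; the table itself gives none.

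Calls were recomputed with library totals as the scale, which moves every log2 fold change at Pe day 0 by 0.67 and at Pe day 3 by 0.03 with standard errors kept, without a filter on low means, at a mean of at least 5 CPM, and at a minimum 2-fold change. Added after seeing the data were centring on the median gene, totals without the 20 most abundant genes, the bound on the standard error, and, for the gene lists, every setting tried (a preset correlation of 0.05, ranks, library totals and the minimum of 5 CPM). Ribosomal proteins and proteases were each set against 50 genes nearest in transcript length and mean count, with a bootstrap interval over genes, which treats genes as independent. Shared libraries were simulated in 100 draws without effects for the correlations and covariances, and in 100 draws with the day 0 fold changes as estimated and no change at day 3. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.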

Results

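Total RNA from the adult midgut of wild-type Oregon-R Drosophila melanogaster was turned into libraries in 3 groups of 2. Flies aged 4 to 5 days had received sucrose (Mock day 0) or a treatment that the labels call Pe, an abbreviation they do not spell out (Pe day 0). Flies aged 7 to 8 days formed the group labelled Pe day 3, and the labels name no sucrose group at that age. Pe day 3 and Mock thus differ in treatment, day and age together. The design text frames the series as a look at how regeneration of the midgut begins and how it ends. The deposited values were the authors' gene-level comparisons of each Pe group with Mock, and the depth recovered from them was between 17.6e6 and 20.1e6 reads per library. The header of that table names no groups. Which comparison is day 0 and which is day 3 was read from the order of the groups in the table's title, and every direction below rests on that order.

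The first comparison asked what changed in the midgut right after Pe, at the same age as Mock. Genes of the JAK-STAT and EGFR pathways were among those that rose. The cytokine genes upd2 (log2 fold change 7.80, SE 0.46) and upd3 (7.43, SE 0.31) of the JAK-STAT pathway were 223-fold and 173-fold higher at Pe day 0 than in Mock in the authors' deposited table. Socs36E, a target and inhibitor of that pathway, rose 15.7-fold in the authors' deposited table (3.97, SE 0.17). The EGFR ligand genes vn (4.36, SE 0.35) and Krn (2.01, SE 0.14) also rose in the authors' deposited table. Of the 10 tested members of the JAK-STAT list 5 rose and 0 fell, 5 of them also when adjusted over the list alone and 8 with library totals, and the list stood above other genes (adjusted p = 1.62e-05, limma's camera test). The EGFR list had 8 higher and 2 lower genes of 12, the lower ones being Egfr (-1.35, SE 0.19) and spi (-0.67, SE 0.14) in the authors' deposited table. Library totals move every gene up by 0.67 at day 0, so the median rises by that much in any list. Over all genes 5545 were then called higher, against 2391 as deposited. With library totals the fall of spi ended and 8 genes of the EGFR list were higher and 1 lower, at a median of 1.58 against 0.91. Its camera call (adjusted p = 0.0390) was lost with library totals as the scale (adjusted p = 0.0805), with a preset correlation of 0.05 (adjusted p = 0.100) and among genes of at least 5 CPM (adjusted p = 0.118).

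Genes of wounding and stress responses moved with them. Of 12 genes in the JNK and wound response list 9 rose and 1 fell (adjusted p = 1.10e-11, camera test), with the same counts when adjusted over the list alone. Among them Gadd45 rose 43.4-fold and Ets21C, a transcription factor gene, 34.2-fold in the authors' deposited table, while egr, which encodes a TNF ligand, fell by 0.84 on the log2 scale (SE 0.22), a call lost with library totals (-0.17), where the list had 10 higher and 0 lower genes. The JNK phosphatase gene puc (1.29, SE 0.14), the matrix metalloproteinase gene Mmp1 (1.12, SE 0.15) and kay, the fly Fos gene (2.01, SE 0.12), were higher in the authors' deposited table. Heat shock genes were higher in 11 of 15 cases and lower in 1, the last being Hsp83 (-0.34, SE 0.15), with Hsp22 at 5.51 (SE 0.44) and Hsp23 at 4.24 (SE 0.55) in the authors' deposited table. The heat shock list was called (adjusted p = 0.00875, camera test), a call against other genes that was lost with library totals (adjusted p = 0.148). The members themselves were then 13 higher and 0 lower with a median of 4.90 against 4.24, and Hsp83 changed direction, to 0.33. Hsp70Aa was at 0 estimated reads in Mock and at least 150-fold higher at Pe day 0, and Rcd-1r, likewise at 0, at least 84.2-fold higher, both against a floor of 3 counts over the Mock group. Turandot stress peptide genes rose in 4 of 5 cases, TotC to 112-fold and TotA to 28.4-fold in the authors' deposited table. That list (adjusted p = 0.0159, camera test) lost its call with library totals (adjusted p = 0.162) and had under 4 members at 5 CPM or more. With library totals 4 members stayed higher, and the same shift moved the median from 5.55 to 6.22.

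Detoxification genes went both ways. Of 31 glutathione S-transferase genes 15 rose and 11 fell, 16 and 11 when adjusted over the list alone (adjusted p = 0.00330 towards higher, camera test); with library totals 18 were higher and 2 lower, and the call was lost on ranks of the statistics. GstD5 rose 83.4-fold, GstD9 38.5-fold and GstD1 4.25-fold in the authors' deposited table, while GstT4 (-2.61, SE 0.17) and GstE12 (-1.49, SE 0.10) fell. Cytochrome P450 genes were higher in 19 and lower in 31 of 77 cases, which turned to 31 and 19 with library totals, and the list was not called (adjusted p = 0.302, camera test). Cyp6d2 rose 16.1-fold in the authors' deposited table, whereas Cyp4d1 (-5.18, SE 0.20) and Cyp6w1 (-5.01, SE 0.23) fell.

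Genes of the cell cycle rose. In the DNA replication list 16 of 17 genes were higher and 0 lower (adjusted p = 0.000110, camera test), with the same counts when adjusted over the list alone; PCNA, the replication clamp, rose 5.00-fold and RnrL, a ribonucleotide reductase subunit, 7.23-fold in the authors' deposited table. In the mitotic list 12 of 21 genes were higher and 0 lower (adjusted p = 0.0110, camera test), and the call was lost with library totals (adjusted p = 0.148), a preset correlation of 0.05 (adjusted p = 0.0653) and a minimum of 5 CPM (adjusted p = 0.121). With library totals 19 members were higher and 0 lower, and the median was 2.10 against 1.43. Klp10A (1.47, SE 0.12) and feo (2.15, SE 0.35) were among the risers in the authors' deposited table, where CycB (0.43, SE 0.43) and the Cdc25 gene stg (1.40, SE 0.65) did not pass the test, though both did with library totals. Stem cell and enteroblast markers split, with 4 of 14 higher and 6 lower (7 and 3 with library totals), and the list was not called (adjusted p = 0.888, camera test). In the authors' deposited table the Notch ligand gene Dl was 3.13-fold higher (1.64, SE 0.27), while esg (-1.25, SE 0.18) and mira (-1.76, SE 0.15) were lower.

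Digestive protease genes fell together. All 27 tested genes for trypsins and chymotrypsin-like proteases were lower at Pe day 0, 27 also when adjusted over the list alone, with a median log2 fold change of -2.33 (adjusted p = 4.08e-52, camera test); 26 were still lower with library totals. Jon99Fii was 29.9-fold, Jon99Fi 21.7-fold, zetaTry 18.8-fold and betaTry 3.31-fold lower in the authors' deposited table. Among the most reduced genes of the whole comparison were Ser8, which encodes another serine protease (-6.35, SE 0.24), and the lysosomal alpha-mannosidase genes LManII (-6.62, SE 0.55) and LManVI (-6.45, SE 0.89), in the authors' deposited table. The authors' deposited table also placed lcs (-8.54, SE 1.79), whe (-8.39, SE 1.82) and the maltase gene Mal-B1 (-6.24, SE 2.08) there, with wide errors. The lipase gene mag fell by 5.27 (SE 0.15) in the authors' deposited table. Going the other way, LysX, a lysozyme gene, was 203-fold and Drsl3, a gene of the drosomycin family, 136-fold higher in the authors' deposited table. The carbohydrate and lipid digestion list, which holds mag and LysX, had 5 higher and 7 lower genes of 20 (8 and 6 with library totals; adjusted p = 0.426, camera test).

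Genes for the cytosolic ribosome fell together. Of 80 ribosomal protein genes 78 were lower and 0 higher, 78 also when adjusted over the list alone, with a median of -1.15 (adjusted p = 1.39e-45, camera test). RpS6 (-1.36, SE 0.08) and RpL41 (-1.39, SE 0.10) fell in the authors' deposited table. With library totals 76 stayed lower and the median was -0.48; against other genes of like transcript length and abundance the median difference was -0.12, or -0.24 with the proteases left out of those genes. Of 65 genes of the mitochondrial respiratory chain 57 were lower, 58 when adjusted over the list alone (adjusted p = 2.98e-09, camera test), but with library totals 11 were lower and 4 higher.

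Markers of other cell types of the gut wall also moved. Visceral muscle genes were lower in 12 of 15 cases with a median of -1.09 (adjusted p = 0.000167, camera test), and adjusted over the list alone 12 were lower and 1 higher; with library totals 7 were lower and 2 higher. Mlc2 (-1.40, SE 0.14) and up, which encodes troponin T (-1.31, SE 0.12), fell in the authors' deposited table. Enteroendocrine genes were lower in 10 and higher in 1 of 14 cases (adjusted p = 0.000750, camera test), and in 5 and 3 with library totals. The peptide hormone genes AstC (-2.70, SE 0.11) and AstA (-1.27, SE 0.13) fell and ITP (1.81, SE 0.17) rose in the authors' deposited table, where pros, a transcription factor gene of enteroendocrine cells, stood at -0.58 (SE 0.25; 0.09 with library totals). Enterocyte identity genes went both ways, 4 higher and 4 lower of 10 (5 and 5 when adjusted over the list alone, 5 and 2 with library totals; adjusted p = 0.888, camera test). In the authors' deposited table mesh (1.26, SE 0.13) and nub (1.19, SE 0.11) were higher, and Myo31DF (-0.44, SE 0.13; 0.22 with library totals) and LManI (-5.94, SE 0.49) lower. Haemocyte genes were lower in 4 of 10 cases (adjusted p = 0.518, camera test), with 1 higher and 1 lower with library totals, and the list was called on ranks of the statistics (adjusted p = 0.0462). Yp1 (-2.05, SE 0.27) and Yp2 (-2.11, SE 0.50), yolk protein genes of the fat body, fell in the authors' deposited table, and 3 of 9 genes of the fat body and female reproductive list were lower (2 with library totals; adjusted p = 0.426, camera test). Neuronal genes had 1 higher and 1 lower of 8 (2 and 0 with library totals; adjusted p = 0.888, camera test), and genes of the Malpighian tubule and hindgut 1 higher and 3 lower of 7 (1 and 2 with library totals; adjusted p = 0.531, camera test).

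The remaining lists were not called at day 0 by the camera test. Antimicrobial peptide genes had 2 higher of 11, 1 when adjusted over the list alone (adjusted p = 0.743), at low levels: DptA was at 3.86 (SE 1.21) with a mean of 9.98 normalized counts over all libraries in the authors' deposited table. In the Imd list 6 of 12 genes were higher and 4 lower (adjusted p = 0.830). Rel, the NF-kappaB factor of that pathway, rose in the authors' deposited table (1.85, SE 0.13), the amidase genes PGRP-SC1a (-5.02, SE 0.25) and PGRP-SC2 (-2.61, SE 0.19) fell, and pirk, a negative regulator, was at 0.92 (SE 0.56), passing only with library totals. The BMP and activin list had 3 higher and 7 lower of 15 (7 and 2 with library totals; adjusted p = 0.750), with the ligand gene dpp lower (-1.38, SE 0.22) and the inhibitor gene Dad higher (1.19, SE 0.13) in the authors' deposited table. Redox enzymes had 4 higher and 5 lower of 13 (7 and 3 with library totals; adjusted p = 0.569), and the unfolded protein and integrated stress list 4 and 7 of 14 (8 and 4 with library totals; adjusted p = 0.562). Peritrophic matrix and mucin genes had 3 higher and 2 lower of 9 (adjusted p = 0.830), and Wnt and Hippo genes 3 and 5 of 11 (7 and 2 with library totals; adjusted p = 0.830). Insulin and TOR genes had 3 higher and 2 lower of 11 (adjusted p = 0.888), microRNA and small RNA pathway genes 4 and 3 of 11 (adjusted p = 0.750), and ribosome biogenesis genes 3 and 2 of 17 (adjusted p = 0.888). With library totals these became 7 and 0, 8 and 0, and 16 and 0. Dcr-2, the Dicer of the short interfering RNA pathway, rose in the authors' deposited table (1.11, SE 0.14).

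**Figure D1:**
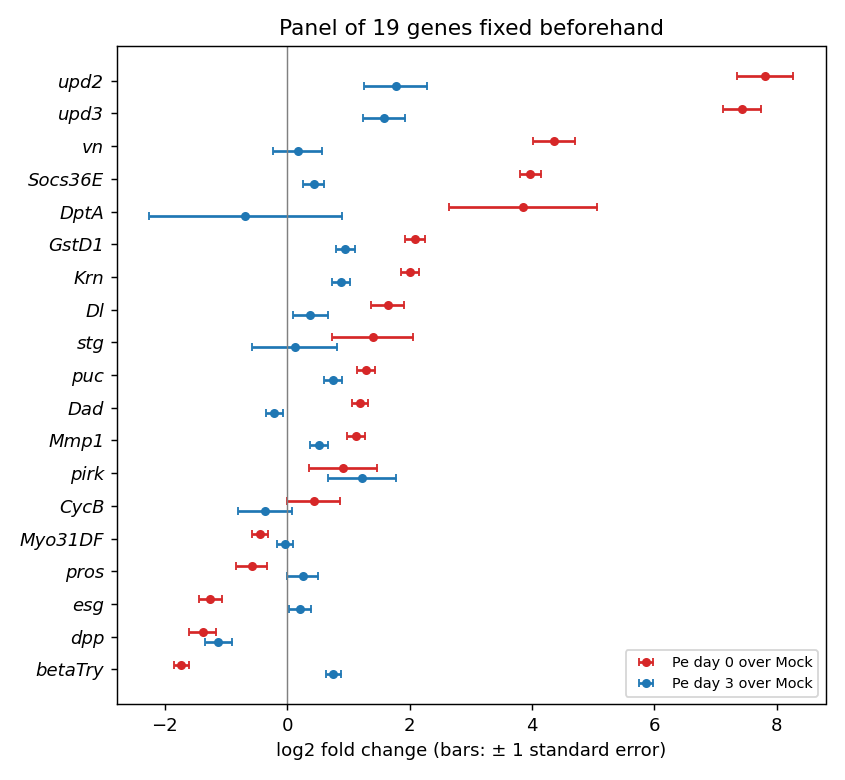
Log2 fold changes over Mock of the 19 genes named before the data were examined, at Pe day 0 (red) and Pe day 3 (blue), from the authors' deposited table; bars are ± 1 standard error of the fit. At day 0 upd2 and upd3 lie at 7.80 and 7.43 and betaTry at -1.73, and at day 3 betaTry lies at 0.75.

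In all, 4846 of 10393 tested genes passed an adjusted p of 0.05 in the authors' deposited table at Pe day 0, 2391 higher and 2455 lower, and 2294 of them changed at least 2-fold. The split depends on the scale. Total normalized counts at Pe day 0 stood at -0.67 (log2) against Mock, and at -0.495 without the 20 most abundant genes. The 27 proteases alone held 10.7% of all counts in Mock against 4.23% at Pe day 0. With library totals as the scale 5545 genes were higher and 932 lower. Reads of near-identical copies (the Hsp70, trypsin, Jonah, LMan, lysozyme, PGRP-SC1 and GstD families) could have been divided among them by the authors' counting, so single members are uncertain.

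The second comparison asked how far the midgut at Pe day 3 stood from Mock. Glutathione S-transferase genes were among those higher than Mock. In the authors' deposited table GstD9 was still 17.0-fold (4.09, SE 0.20) and GstD5 4.33-fold higher than Mock, Arc1, a gene derived from a retrotransposon Gag, 14.2-fold, and ImpL2, which encodes a secreted insulin antagonist, 4.43-fold. The authors' deposited table also had gammaTry 6.24-fold (2.64, SE 0.17) and cac, a calcium channel gene of neurons, 4.00-fold higher. It was the 1 gene called of 6 in the neuronal list (adjusted p = 0.187, camera test), and the eye photoreceptor genes ninaE (7.13, SE 1.66) and Arr2 (6.72, SE 2.14), chosen after their values were seen, were higher in the authors' deposited table. The errors of ninaE and Arr2 were wide against a median SE of 0.18 over tested genes. Without values per library it cannot be told whether 1 library carried their rise. On the lower side stood the neighbouring mannosidase genes LManIII (-4.94, SE 0.21), LManIV (-6.18, SE 0.60) and LManV (-3.92, SE 0.58), with lcs (-5.33, SE 1.75), whe (-5.33, SE 1.79) and Ag5r (-3.68, SE 1.16) in the authors' deposited table. LManIII to LManVI lie side by side on chromosome 2L (8765273 to 8781252, minus strand, BDGP6.54), apart from LManI and LManII (10452677 to 10462472), and LManVI was also lower (-2.63, SE 0.88) in the authors' deposited table, whereas LManI (-0.54, SE 0.48) and LManII (-0.94, SE 0.55) did not pass.

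By list, 10 of 29 glutathione S-transferase genes were higher and 2 lower at day 3 (adjusted p = 6.30e-07, camera test), and 5 of 9 genes of the JNK and wound response list higher and 0 lower (adjusted p = 0.000680), with the same counts when adjusted over the list alone. In the authors' deposited table puc (0.75, SE 0.14), Mmp1 (0.52, SE 0.15), upd3 (1.58, SE 0.35), upd2 (1.77, SE 0.51), Krn (0.88, SE 0.15) and GstD1 (0.95, SE 0.16) were higher, and Socs36E (0.44, SE 0.17), vn (0.17, SE 0.40) and Dl (0.38, SE 0.29) did not pass, Socs36E doing so with library totals. Enteroendocrine genes were higher in 6 of 13 cases and lower in 0 (adjusted p = 0.0227, camera test), among them CCHa1 (0.63, SE 0.17) and CCHa2 (0.49, SE 0.13) in the authors' deposited table. That call was lost with a preset correlation of 0.05 (adjusted p = 0.0870) and at 5 CPM (adjusted p = 0.0512). Peritrophic matrix and mucin genes were higher in 3 of 5 cases (adjusted p = 0.000680, camera test), with Peritrophin-15a at 0.59 (SE 0.10) and Peritrophin-15b at 1.05 (SE 0.14) in the authors' deposited table. The EGFR list, with 4 higher of 10, was called (adjusted p = 0.0485, camera test) but not with library totals (adjusted p = 0.0524), on ranks (adjusted p = 0.111), with a preset correlation of 0.05 (adjusted p = 0.119) or at 5 CPM (adjusted p = 0.115). Ribosomal protein genes were lower in 75 of 79 cases, 78 when adjusted over the list alone, with a median of -0.44 (adjusted p = 2.87e-39, camera test) and 72 lower with library totals. Ribosome biogenesis genes were lower in 6 of 17 cases, 8 when adjusted over the list alone (adjusted p = 0.000351, camera test), with hoip at -0.95 (SE 0.14) and Nlp at -0.91 (SE 0.12) in the authors' deposited table.

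The other lists with at least 4 tested members were not called at day 3. Antimicrobial peptide and Turandot genes had fewer than 4 tested members at day 3 and between the days, so those lists were not tested there. The 27 proteases had 7 higher and 5 lower members around a median of -0.01 (0.02 with library totals; adjusted p = 0.145, camera test). None of 58 respiratory chain genes (median -0.12) and none of 15 visceral muscle genes (median -0.01) passed, although the former list was called on ranks (adjusted p = 0.00363, camera test), as was heat shock (adjusted p = 0.0425), where 3 of 14 genes were higher and 1 lower. DNA replication and mitotic genes each had 1 higher and 0 lower, of 17 and 19. Of the other panel genes, dpp was lower (-1.12, SE 0.23) and betaTry higher (0.75, SE 0.12) in the authors' deposited table. There esg (0.21, SE 0.18), pros (0.25, SE 0.25), Myo31DF (-0.03, SE 0.13), pirk (1.23, SE 0.56), stg (0.13, SE 0.69), CycB (-0.36, SE 0.44) and Dad (-0.21, SE 0.14) were not called. DptA (-0.68, SE 1.57) had a mean below the limit of 20.8 and was not tested at day 3. Across all genes, 1470 of 8316 passed in the authors' deposited table, 728 higher and 742 lower, and 239 changed at least 2-fold. With library totals left without the 20 most abundant genes, a scale chosen after seeing the data, 955 were higher and 561 lower. Day and age differ from Mock along with treatment in this comparison.

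**Figure D2:**
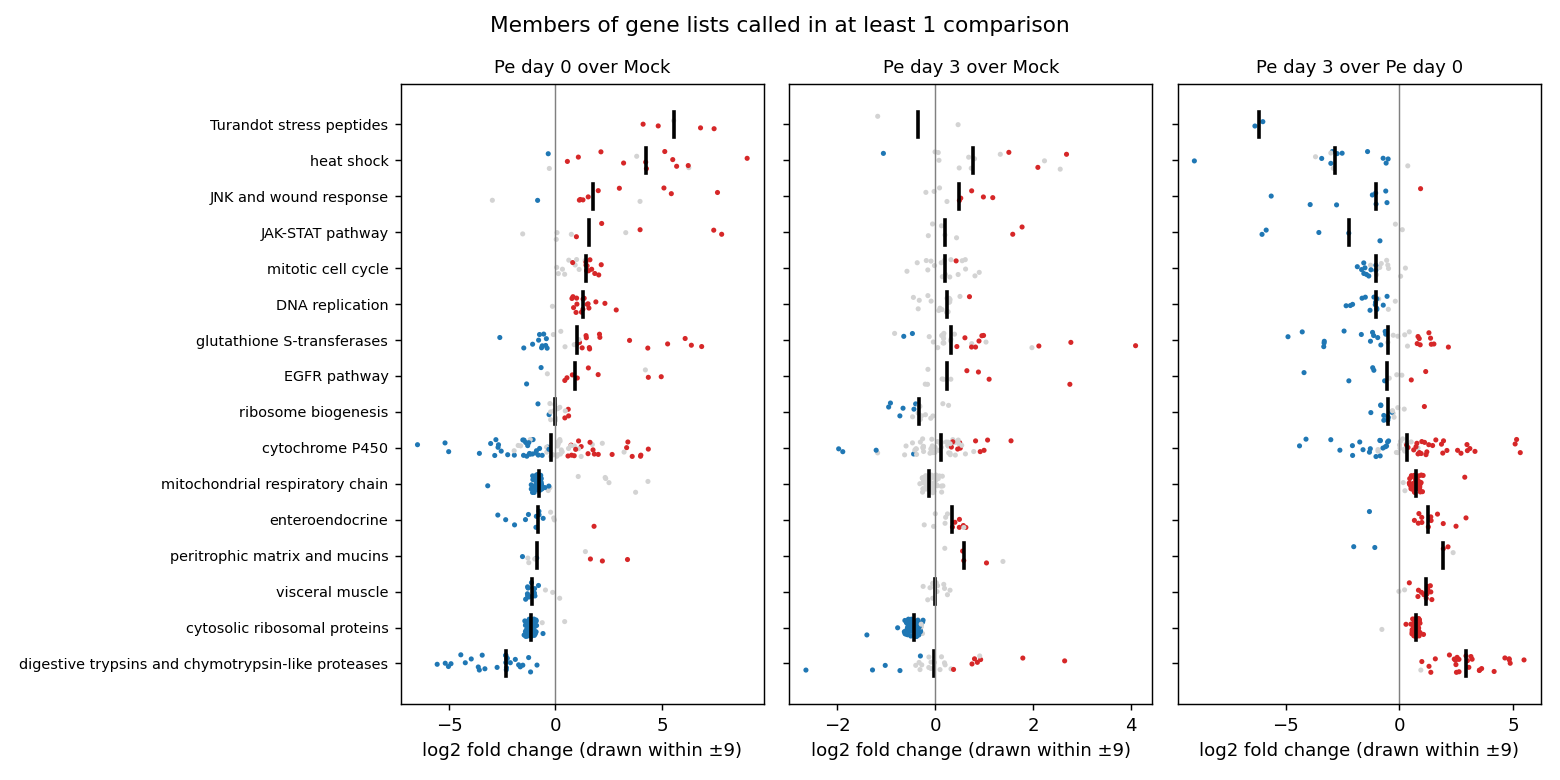
Log2 fold changes of the tested members of the 16 gene lists called in at least 1 comparison, for Pe day 0 over Mock, Pe day 3 over Mock and Pe day 3 over Pe day 0; each dot is a gene, red for called higher, blue for called lower and grey for not called, black bars are list medians, and the 3 horizontal axes differ in range. The digestive proteases have medians of -2.33, -0.01 and 2.92 in turn, and under library totals all dots of all lists shift up by 0.67 at day 0.

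The third comparison, Pe day 3 against Pe day 0, was computed from the other 2 and asked how the day 0 state had changed by day 3. Digestive protease genes were higher at day 3. Jon25Biii was 44.2-fold higher than at day 0 (log2 fold change 5.47, SE 0.19), Ser8 66.6-fold (6.06, SE 0.24), LManII 51.2-fold (5.68, SE 0.55) and LManI 42.0-fold (5.39, SE 0.49). The cytochrome P450 genes Cyp6w1 (5.14, SE 0.23) and Cyp4d1 (5.08, SE 0.20) were the other leaders among named genes. Of 27 protease genes 26 were higher, 27 when adjusted over the list alone, with a median of 2.92 (adjusted p = 1.34e-58, camera test), and 25 with library totals. The carbohydrate and lipid digestion list had 6 higher and 6 lower genes of 19 (6 and 10 with library totals) and was not called (adjusted p = 0.957, camera test). Among the genes that fell were Drsl3 (-7.11, SE 0.36), TotC (-6.34, SE 0.55), LysX (-6.27, SE 0.32), upd2 (-6.03, SE 0.31) and upd3 (-5.85, SE 0.22). Hsp70Aa and Rcd-1r, both at 0 estimated reads at day 3, were at least 157-fold and 88.3-fold lower than at day 0 against the floor of 3 counts over the group.

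The JAK-STAT, JNK and DNA replication lists were lower at day 3 than at day 0. JAK-STAT genes were lower in 5 of 7 cases (adjusted p = 3.68e-08, camera test), JNK and wound response genes in 8 of 9 with 1 higher (adjusted p = 8.23e-10), and DNA replication genes in 14 of 17, 15 when adjusted over the list alone (adjusted p = 0.000199). With library totals 7, 8 and 17 of them were lower. Socs36E (-3.54, SE 0.17), Gadd45 (-5.63, SE 0.13), vn (-4.19, SE 0.33), Krn (-1.12, SE 0.14) and Dl (-1.27, SE 0.26) fell. The EGFR list, which holds vn and Krn, had 2 higher and 5 lower genes of 10 (1 and 8 with library totals) and was not called (adjusted p = 0.206, camera test). Heat shock genes were lower in 10 of 14 cases (adjusted p = 0.0241, camera test) and mitotic genes in 10 of 19 (adjusted p = 0.0266, camera test). Both calls were lost with library totals (adjusted p = 0.339 and 0.345) and with a preset correlation of 0.05 (adjusted p = 0.0864 and 0.117), the mitotic one also at 5 CPM (adjusted p = 0.114). Library totals move every log2 fold change between the days down by 0.64. With them 11 heat shock genes were lower, at a median of -3.46 against -2.82, and 17 mitotic genes, at a median of -1.67 against -1.04. Of the panel, puc (-0.55, SE 0.14), Mmp1 (-0.60, SE 0.14), GstD1 (-1.13, SE 0.16) and Dad (-1.40, SE 0.13) fell, and dpp (0.26, SE 0.23), pirk (0.31, SE 0.56), stg (-1.27, SE 0.65) and CycB (-0.80, SE 0.43) were not called, stg and CycB being lower with library totals.

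Higher at day 3 than at day 0 were 12 of 13 enteroendocrine genes, with 1 lower (adjusted p = 1.79e-06, camera test; 9 and 1 with library totals), and 13 of 15 visceral muscle genes (adjusted p = 0.000113; 8 higher and 1 lower with library totals). AstC rose by 2.48 (SE 0.11), AstA by 1.67 (SE 0.12) and Mlc2 by 1.42 (SE 0.14), and esg by 1.46 (SE 0.18), betaTry by 2.48 (SE 0.12), pros by 0.83 (SE 0.25; 0.19 and not called with library totals) and Myo31DF by 0.41 (SE 0.13; -0.23 with library totals). Ribosomal protein genes were higher in 78 of 79 cases (median 0.72; adjusted p = 4.65e-17, camera test) and respiratory chain genes in 56 of 58, 57 when adjusted over the list alone (adjusted p = 1.12e-08), but with library totals the counts were 10 higher and 2 lower, and 7 higher and 2 lower. Cytochrome P450 genes were higher in 28 and lower in 19 of 61 cases (20 and 28 with library totals), called towards higher (adjusted p = 0.0266, camera test) but not with a preset correlation of 0.05 (adjusted p = 0.252) or on ranks (adjusted p = 0.203). Ribosome biogenesis genes, lower in 10 of 17 cases, were not called (adjusted p = 0.104, camera test), though they were on ranks and with library totals.

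Of 8316 genes 4381 passed between the days, 2279 higher and 2102 lower at day 3, and 778 higher and 5250 lower with library totals. A test for any difference among the 3 groups called 5129.

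Most genes called at day 0 went the other way between day 0 and day 3. Of 4608 genes called at Pe day 0 among those tested in both comparisons, 3605 (78.2%) were called in the opposite direction from day 0 to day 3: 1710 genes that had risen, upd3, Gadd45 and PCNA among them, and 1895 that had fallen, such as Jon25Biii and AstC. Independent lists of these sizes would share 561 and 654 genes, and part of the excess may come from the shared Pe day 0 libraries. The share was 59.6% with an upper bound on the standard error. Another 14 genes rose further and 24 fell further. The fold changes of both comparisons had a covariance of -1.38 across genes, which are not independent replicates, against -0.05 in simulation (correlation -0.88 against -0.47).

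Against Mock, 454 genes were higher at both days and 522 lower at both, such as GstD9, Arc1 and ImpL2 on one side and LManV, PGRP-SC1a and dpp on the other. Independent lists would share 194 and 213, and part of the excess may come from the shared Mock libraries. The covariance of these fold changes was 0.33 against 0.06 in simulation (correlation 0.41 against 0.52). A further 137 genes were lower than Mock at day 0 and higher at day 3, and 36 the reverse, where independent lists would share 209 and 198. The first set held gammaTry, deltaTry, betaTry, Jon99Fi, Peritrophin-15b and cac, and with library totals 40 of the 137 kept both calls, among them deltaTry, betaTry and Jon99Fi but not gammaTry, Peritrophin-15b or cac. The second held Mal-A3, which kept both, as did 29 of the 36.

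**Figure D3:**
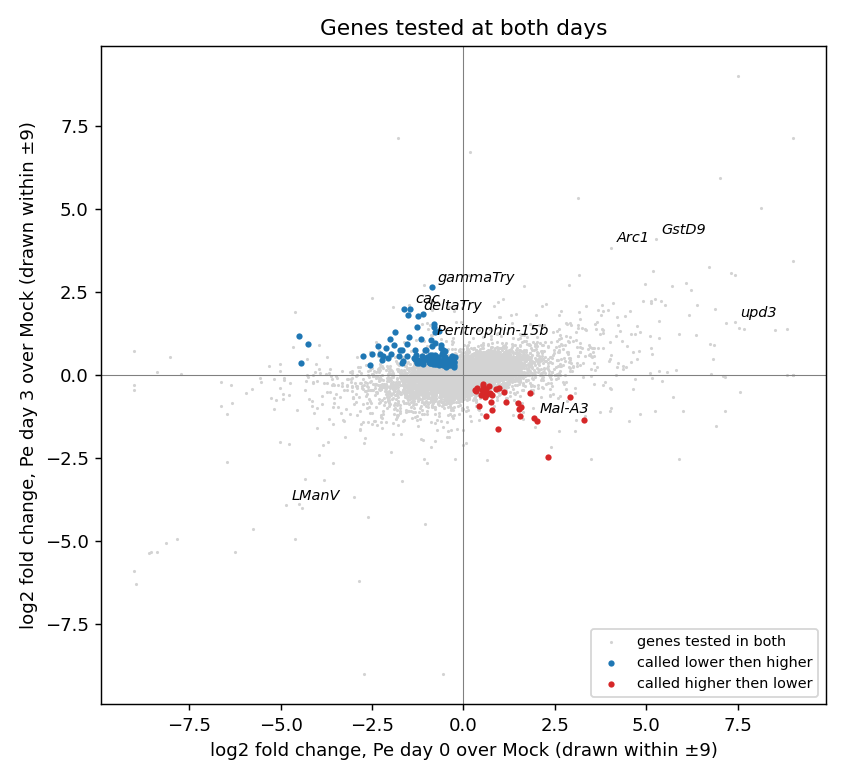
Log2 fold change over Mock of each gene tested at both days, day 0 on the horizontal axis and day 3 on the vertical axis, with values beyond 9 drawn at 9. The 137 genes called lower at day 0 and higher at day 3 are blue and the 36 called the other way red; with library totals as the scale 40 and 29 of them keep both calls.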

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

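The tests of enterocyte share, of scale for the proteases and ribosomal proteins, and of matched genes without the proteases were chosen after the result was seen. The responses to Pe at the 2 days, each against Mock, differed in direction for 137 genes that were lower at day 0 and higher at day 3 and for 36 genes with the reverse order. Independent lists would share 209 and 198 such genes, so both sets were smaller than that. The difference between the days was called in each of the 137 and 36 genes, which the choice of opposite calls against Mock all but fixed. Named genes with this difference between groups, with the log2 fold change of Pe day 3 over Pe day 0, were Jon99Fi (4.82), gammaTry (3.51), cac (3.46), deltaTry (3.05), betaTry (2.48), Peritrophin-15a (2.13), Peritrophin-15b (1.93), AstA (1.67), CCHa2 (1.39) and Mal-A3 (-3.24).

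Scaling by size factors could account for many of the 137 genes. With library totals 40 kept both calls (gammaTry, cac, Peritrophin-15b and CCHa2 did not), which fits that explanation and leaves it open. Noise of the shared Mock libraries moves both comparisons the same way (simulated covariance 0.06) and does not enter the difference between the days. That difference was called in all 137, but the choice of genes called on opposite sides of Mock all but fixed this, so it adds no support. Whether noise of the Mock libraries placed Mock between the days is undecided, since the simulation (0 such genes) called at most 2 genes at day 3 in any of 100 draws. A biological explanation, the change from the first day to day 3 after Pe, cannot be told apart from age in these groups.

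The fall of the 27 digestive proteases at day 0 could reflect a lower share of enterocytes. The median of the enterocyte identity genes lay 2.26 above that of the proteases (permutation p = 0.00213). That p shuffles genes, which are not independent, and does not measure the spread between libraries. Visceral muscle genes had a median of -1.09, or -0.43 with library totals (7 lower and 2 higher of 15). The muscle values cannot decide this, since a larger share of any other source of RNA would lower muscle and enterocyte genes alike. The gap between the medians argues against a lower share of enterocytes alone, as far as the identity list marks enterocytes. Its members ran from -5.94 to 1.26, with 4 called higher and 4 lower. Scale as the whole source is argued against too, as 26 of the 27 stayed lower with library totals, at a median of -1.66 against -2.33. So are transcript length and abundance as the whole source, since the median difference to 50 genes alike in both was -1.19 (95% interval -2.87 to -1.16). A response to Pe stays open, as do explanations not tested here.

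The fall of ribosomal protein genes at day 0 could come from scale or from transcript length and abundance. With library totals 76 of 80 stayed lower, which argues against scale as the whole source. The median moved from -1.15 to -0.48, so scale stays open for a part of the fall. From day 0 to day 3 the return, 78 higher of 79, became 10 higher and 2 lower with library totals. Against 50 genes of like length and abundance the median difference was -0.12 (95% interval -0.18 to -0.05), and -0.24 (-0.29 to -0.20) with the proteases left out of those genes. Genes alike in length and abundance thus fell nearly as far, which fits a bias by length or abundance. The match cannot tell such a bias from a change that these genes share for another reason, so the bias stays open. A biological explanation by Pe was not tested apart from it.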

How the results depend on the processing

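The totals without the 20 most abundant genes, the centring on the median gene, the bound on the standard error and every setting tried for the gene lists were chosen after the result was seen. The share of day 0 calls that were called in the opposite direction from day 0 to day 3 also counts genes still on the same side of Mock at day 3. With library totals (planned) that share rose from 78.2% to 87.9%, and with totals left without the 20 most abundant genes to 83.2%. Without a filter it was 76.1%, at a 2-fold minimum 67.5% and with the bound on the standard error 59.6%. The cause of these changes in the share was not tested. The fewer calls of the stricter settings account for their lower counts: a 2-fold minimum left 2294 genes at Pe day 0, 239 at Pe day 3, 1674 between the days and 2310 among all groups. No other setting moved the total of called genes or lists by over 1.5 times, but library totals moved the splits: 5545 genes higher and 932 lower at Pe day 0 (2391 and 2455 as deposited), 778 and 5250 between the days (2279 and 2102), and 4 lists called higher at Pe day 0 in place of 8. Totals without the 20 most abundant genes gave 4721 and 1241 at Pe day 0 and 1169 and 4255 between the days. Of the 4846 calls at Pe day 0, 3323 were the same with library totals and 180 turned over. Of the named genes called in a comparison, those whose direction changed there were Hsp83 at Pe day 0 (0.33 with library totals, 0.16 without the 20 most abundant genes), Myo31DF at Pe day 0 (0.22 and 0.0516) and between the days (-0.23 and -0.0124), and, with library totals, pros at Pe day 0 (0.0915) and RpL41 (-0.0137) and spi (-0.12) between the days. The shift added by the scale itself accounts for these. No paired analysis was possible because the table holds no values per library. For the same reason the other planned settings were not run: the edgeR test with TMM or size factors, TMM without the 20 most abundant genes, fits of 2 groups, a replicate block, a library left out, other pseudocounts, prior counts or mean filters, fry, and an estimated correlation. The authors' filter left genes below a mean of 1.24 untested at Pe day 0 and below 20.8 at Pe day 3. The limit of 20.8 was also taken over here for the comparison between the days and for the joint test. The part of depth in these limits was not tested.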

Other observations

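The 8 gene families here were chosen and tested after the result was seen, with camera and adjustment over these families. Nucleoporin genes were higher at Pe day 0 in 16 of 19 cases (median 0.73, adjusted p = 0.00116) and lower in 17 from day 0 to day 3 (adjusted p = 0.00125). All 8 genes for chaperonin subunits were higher at day 0 (median 0.54, adjusted p = 0.00427) and all 8 lower at day 3 than at day 0. Against Mock at day 3, 3 of them were lower and 0 higher (median -0.24, adjusted p = 0.00647). With library totals 2 were lower there (adjusted p = 0.0102). Peroxin genes were lower in 10 of 13 cases at day 0 (adjusted p = 0.00216) and genes for vacuolar proton pump subunits lower in 20 and higher in 2 of 26 (adjusted p = 0.00427), but with library totals the former had 3 higher and 4 lower, the latter 4 higher and 0 lower, and neither was called (adjusted p = 0.0642). The proton pump genes were higher than Mock at day 3 in 3 of 21 cases (adjusted p = 0.00487) and higher from day 0 to day 3 in 19 (adjusted p = 7.89e-06), and with library totals in 6 (adjusted p = 0.00332) and in 9 with 2 lower (adjusted p = 0.000401). Genes of the mitochondrial genome were lower in 11 of 13 cases at day 0 (median -1.03, adjusted p = 0.000262), and in 7 with library totals (median -0.36, adjusted p = 0.00224).

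Nuclear genes for mitochondrial ribosomal proteins had 4 higher and 8 lower of 73 at day 0 (54 and 0 with library totals), and 37 lower and 0 higher at day 3 against Mock (median -0.44, adjusted p = 4.13e-15). At day 3 against Mock genes of the proteasome regulatory particle were higher in 5 of 19 cases (adjusted p = 0.00447). Of 6 tested eye photoreceptor genes 2, ninaE and Arr2, were higher at day 3 than in Mock, and the family was not called (adjusted p = 0.0734).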
